A study of Mus musculus with 4 samples.

How the data were processed

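The data were 4 Affymetrix mouse arrays with perfect-match probes and 1 biotin label, hybridised with RNA from colon adenoma organoids on a C57BL/6 background. Per the labels' protocols, organoids were grown for 7 days, total RNA was extracted with a TRIzol column kit, and samples with an RNA integrity number of at least 9 were used. From each, 25 ng of total RNA was amplified with a whole transcriptome kit, and 8 µg of cDNA was fragmented and labelled, per the labels' protocols. Amplification from such a small input can compress or widen differences and adds noise to dim probe sets. The deposited values are log2 expression per probe set made by the authors with RMA in the affy package, per the submitters' processing notes; the versions are not given in the sources used here. RMA subtracts a background, applies quantile normalization across arrays and summarises the probes of a set, so array-wide shifts are removed before deposit and low values are compressed towards a floor. No detection calls were used. Array medians ran from 4.91 to 5.04 log2 units, and the number of arrays limits the precision.

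The table held 45141 probe sets, of which 104 were controls and were left out. Genes were named from the platform annotation, which gave 1 gene to 28898 probe sets and several genes to 551, from which no gene was named. A further 15588 probe sets had no gene there and were treated as unnamed. Symbols were checked by Entrez identifier for 28689 probe sets against a RefSeq gene table of the mouse GRCm38.p6 assembly, and 0 symbols changed. That table was used for names alone, and no coordinates are given since no genome build is named for the values. Each of the 17097 genes was represented by its probe set with the highest mean over the 4 arrays. Genes with a mean under the 40th percentile of the probe sets (4.45 log2 units) were left out, leaving 11874. Of 78 named genes, 41 had more than 1 probe set, and 49 of 52 other probe sets above the filter level had the same sign as the chosen ones. No per-sample column of the table was left unused.

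Groups came from the genotype labels, with 2 arrays labelled Apc null and 2 labelled Gata6 null/Apc null. The design text calls them biological replicates without saying whether they came from separate mice. The p-values therefore may not measure the spread between mice. A difference between the mice or cultures of the groups cannot be told apart from one of genotype. The design, the gene lists, the naming rule and the alternatives were fixed before the data were examined, except where the text says otherwise. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend, genotype as the single term), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Every adjusted p without another name is from this fit, is two-sided and has 2 residual degrees of freedom behind it, to which the moderation added 2.83. Standard errors are those of the moderated fit, and standard deviations are over the 2 arrays of a group.

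The labels give a shared batch letter, A or B, to 1 array of each genotype. The differences between batches in the arrays labelled Gata6 null/Apc null and in the Apc null arrays correlated at 0.675 across genes. On the basis of the label the arrays of 1 batch form a pair, which the main fit leaves out. The fit with the batch as a fixed block is therefore given beside a result where it changes a call. It has 1 residual degree of freedom, to which the moderation added 4.99.

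Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 29 lists with 3 or more genes tested. The lists were GATA factors, BMP ligands, BMP receptors and SMADs, BMP antagonists, BMP response genes, intestinal stem cell markers, Wnt target genes, absorptive colonocyte and enterocyte markers, small intestine absorptive genes, goblet, enteroendocrine, tuft and Paneth cell markers, cell cycle genes, fetal and regenerative epithelium genes, Notch pathway genes, gastric and foregut genes, Hox genes of the hindgut, interferon response, inflammatory, p53, hypoxia, cholesterol biosynthesis, unfolded protein response and immediate early genes, and fibroblast, immune, endothelial and Y-linked markers. Members were also adjusted over each list alone. Camera with an estimated correlation and fry were run as alternatives.

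The named genes were Gata6 and Apc, then the 12 genes with the largest increase and the 12 with the largest decrease among those past the threshold with the same sign in both batches, leaving out predicted and clone names. To these were added up to 4 members of each list past the threshold by smallest p, or 2 with the smallest p where none passed, and each BMP ligand past the threshold or with an absolute log2 difference of 1 or more. Of the genes with the largest increase, 1 is not reported here. Genes named outside this rule are marked as chosen after their values were seen.

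The test was checked on simulated data built from the comparison of the 2 groups, with 11874 genes, of which 200 were changed per draw, in 5 draws. Without the block it recovered 2.39% of genes changed by 1 log2 unit, 40% of those changed by 2 and 91.8% of those changed by 4, with 0 false among 445 calls. With the block it recovered 64.8%, 98.5% and 100%, with 98 false among 975 calls (10.1%). In 20 draws with a list shifted by 1 log2 unit at every member, camera called that list 20 times and 4 of 560 tests of unshifted lists. Residuals were drawn independently for each gene. These draws therefore do not check the camera calls where the members of a list are correlated.

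Alternatives were the fixed block, moderation without a trend, robust moderation, no filter on dim genes, a filter at the 60th percentile, the mean of all probe sets of a gene, probe sets without the suffixes for shared sequence, quantile normalization of the deposited values, centring of each array on its median, a threshold of 0.1, and each array left out in turn. Where an array is left out, its group has a single array, which is assumed to vary like the other group. The batches are then unequal between the groups and the fit has no batch term. A difference between the batches therefore enters the genotype difference and its p-value. Added after seeing the data were a fit of all probe sets with and without a gene name and, for each list other than the BMP ligands, the tests with each array left out or with the block.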

Results

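RNA from mouse colon adenoma organoids, which are 3D cultures of tumour epithelium, was measured on 4 Affymetrix arrays. Per the labels the organoids lacked Apc, the Wnt pathway suppressor whose loss starts most intestinal adenomas, after deletion with a tamoxifen-inducible Cre recombinase driven by the Villin promoter in intestinal epithelium. A group of 2 arrays was labelled Apc null and had intact Gata6 alleles. The other group of 2 was labelled Gata6 null/Apc null and also carried floxed alleles of Gata6, a zinc finger transcription factor of endoderm and intestine. Each group had 1 array in batch A and 1 in batch B. All cultures had been grown for 7 days in a medium with EGF at 50 ng/ml. The comparison of the groups addresses which genes, among them the bone morphogenetic protein (BMP) genes, depend on GATA6 in adenoma cells. Array medians lay between 4.91 and 5.04 log2 units over 45141 probe sets, and the arrays correlated with each other at 0.963 to 0.979 across probe sets without controls. Arrays of the same batch correlated at 0.979 in batch A and 0.978 in batch B. Arrays of the same genotype correlated less, at 0.975 for Apc null and 0.976 for Gata6 null/Apc null. After dim genes were left out, 11874 genes were tested. All differences below are given as arrays labelled Gata6 null/Apc null minus arrays labelled Apc null.

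The targeted gene did not separate the groups in the direction of the labels. The brighter Gata6 probe set read 9.37 and 9.40 in the arrays labelled Gata6 null/Apc null of batches A and B, against 8.89 and 8.61 in the arrays labelled Apc null. Its log2 difference was 0.64 (SE 0.19) with a limma adjusted p of 0.418, and an adjusted p of 0.0392 with the batch as a block. The other Gata6 probe set read 9.11 and 9.21 against 8.83 and 8.65. It differed by 0.42 (SE 0.19) and did not pass with the block (limma adjusted p = 0.178 over all probe sets). The position of these probe sets relative to the deleted part of the gene is not known here. A probe set outside that part may stay bright after the deletion, so these values do not check the labels, and every direction reported here rests on the labels alone. Apc, deleted in both groups per the labels, read 8.14 to 8.35 at its brightest probe set on the 4 arrays and differed by -0.10 (SE 0.21, adjusted p = 1.00). The other GATA factors tested included Gata2, which differed by 1.11 (SE 0.24, adjusted p = 0.232, and 0.0129 with the block). The list of GATA factors, with 3 genes tested, had a mean difference of 0.52 and a camera adjusted p of 0.0429, or 0.317 with an estimated correlation. It had no member past the threshold over all genes and 2 higher when adjusted over the list alone, Gata2 and Gata6. Its adjusted p was 0.0595 without the Apc null array of batch A, 0.0584 without that of batch B and 0.0736 without the Gata6 null/Apc null array of batch B.

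The arrays labelled Gata6 null/Apc null had a small set of genes at very high levels that were dim in the Apc null arrays. Mt4, a metallothionein that binds zinc and copper, had the largest increase, from 4.73 ± 0.29 to 11.33 ± 0.23 log2 units (SD, 2 arrays per group), a 97.1-fold difference (log2 6.60, SE 0.27, adjusted p = 0.0125). Apcdd1, a membrane inhibitor of Wnt signalling, was 91.2-fold higher (log2 6.51, SE 0.28), and Wif1, a secreted Wnt-binding inhibitor, was 77.5-fold higher (log2 6.28, SE 0.31). The zinc transporter gene Slc30a2 was 60.1-fold higher. The extracellular proteoglycan gene Spock2 was 55.4-fold higher, the neuronal pentraxin gene Nptx1 37.4-fold and Mgp, the matrix Gla protein that inhibits calcification, 32.8-fold. Prox1, a homeobox transcription factor, was 26.6-fold higher, and a further metallothionein gene, Mt3, was 26.0-fold higher. The calcium-binding protein gene Tesc and the Slit receptor gene Robo1 were 24.4-fold and 24.0-fold higher. The adjusted p-values of these 11 genes lay between 0.0125 and 0.0410. Tesc rests on a probe set that can match shared sequence: without such probe sets its difference was 1.36 (adjusted p = 0.298), and as the mean of all its probe sets 2.98 (adjusted p = 0.0679). Without the Apc null array of batch A, Mgp (adjusted p = 0.0646), Mt3 (0.0892), Tesc (0.0713) and Robo1 (0.0581) did not pass, and without that of batch B Mt3 did not (0.0560). Mt3 also missed the threshold without a trend in the moderation (0.0601) and with the mean of all probe sets per gene (0.0559). The control level of many such genes was near the array floor: 29 of the 62 higher genes had an Apc null mean under the filter level of 4.45, so the size of their folds depends on that floor.

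The genes lower in the arrays labelled Gata6 null/Apc null were fewer. Cldn2, a pore-forming tight junction protein, had the largest decrease, with 10.58 ± 0.06 against 5.65 ± 0.30 (SD, 2 arrays per group), and decreased by 4.93 on the log2 scale (SE 0.25, adjusted p = 0.0126). Lyz2, which encodes a lysozyme, decreased by 4.41 (SE 0.33, adjusted p = 0.0243), at a single probe set that can match shared sequence. Spink4, a protease inhibitor of secretory cells, decreased by 4.30 (SE 0.40, adjusted p = 0.0314). Gcnt3, an enzyme that branches the sugar chains of mucins, decreased by 3.77. The chloride channel gene Cftr decreased by 3.54 and the brush border metalloprotease gene Mep1b decreased by 2.87. Gsta2, a glutathione S-transferase, decreased by 2.85, and Nrp1, a receptor for semaphorins and VEGF, decreased by 2.73. Slc12a8, of the cation chloride cotransporter family, decreased by 2.45 and Glipr1 decreased by 2.35. The galactosyltransferase gene B4galt4 decreased by 2.11 and the cystine transporter gene Slc7a11 decreased by 2.06. The adjusted p-values of these 12 genes lay between 0.0126 and 0.0410. Cftr, Mep1b and Slc7a11 had means of 3.80, 4.01 and 3.83 in the arrays labelled Gata6 null/Apc null, under the filter level of 4.45, so the size of their decreases depends on the array floor.

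Several of these calls were lost under other settings. Gsta2 was called at a probe set that can match shared sequence. Its other probe set differed by -0.09 (adjusted p = 1.00 without shared-sequence probe sets) but read 4.07 to 4.93 on the 4 arrays, near the filter level, so it cannot show whether the decrease belongs to Gsta2. The means of all probe sets, -1.47 for Gsta2 (adjusted p = 0.146) and -1.23 for Slc12a8 (0.0676), include such dim probe sets, for Slc12a8 at 3.21 to 3.30, and say little about the decreases. As the mean of all probe sets, Gcnt3 differed by -3.14 (0.0736) and Slc7a11 by -1.85, and neither passed. Slc7a11 also missed the threshold without a trend in the moderation (0.0612), and B4galt4 with the filter at the 60th percentile (0.0517). Nrp1, Slc12a8, Glipr1 and B4galt4 did not pass whichever of the 4 arrays was left out, with adjusted p-values of 0.0571 to 0.158. Gsta2 did not pass without either Apc null array (0.0907 for batch A and 0.0893 for batch B) or without the Gata6 null/Apc null array of batch B (0.0622). Slc7a11 did not pass without either Apc null array (0.0838 and 0.0893), and Gcnt3 did not without the Gata6 null/Apc null array of batch B (0.0638).

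**Figure D1:**
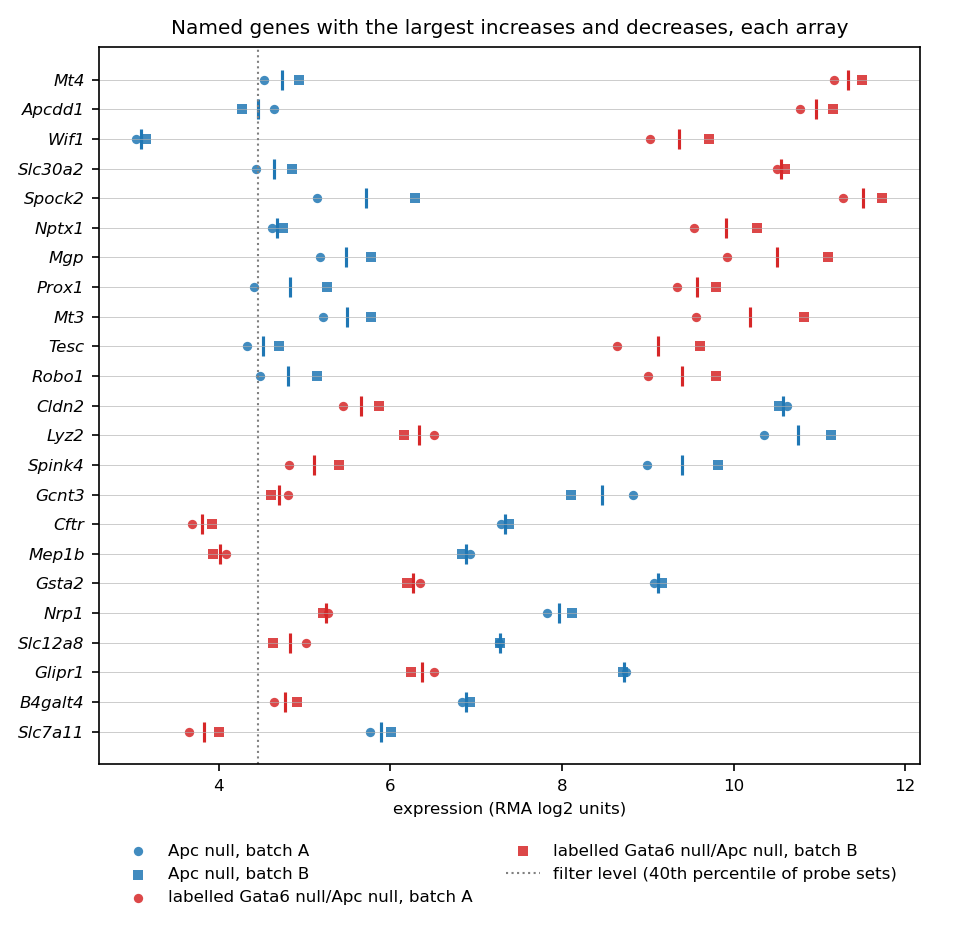
Expression in log2 units (horizontal axis) of the named genes with the largest increases (11) and decreases (12) on each of the 4 arrays, with circles for batch A, squares for batch B, vertical bars for group means and a dotted line at the filter level of 4.45. The arrays labelled Gata6 null/Apc null and Apc null lie apart for each gene, by 6.60 for Mt4 and by -4.93 for Cldn2.

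In all, 77 of 11874 genes passed an adjusted p of 0.05 in limma, 62 higher and 15 lower in the arrays labelled Gata6 null/Apc null, with folds of 2.48 to 97.1. All 77 differed in the same direction in batch A and in batch B. A call needs a group difference that is large against the spread within groups, which here holds the batch difference. The shared direction therefore follows from the selection and is no separate check. Before adjustment, 946 genes had a limma p under 0.05. Across all genes the differences of batch A correlated with those of batch B, which share no array with them, at 0.722, and 63.4% of genes had the same sign in both; genes are not independent replicates. With the batch as a block, 817 genes passed, 464 higher and 353 lower, and all 77 were among them. That fit had 1 residual degree of freedom, and 10.1% of its calls on simulated data were false. The count was 130 without the Gata6 null/Apc null array of batch A, 33 without the Apc null array of batch A and 48 without the Apc null array of batch B.

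**Figure D2:**
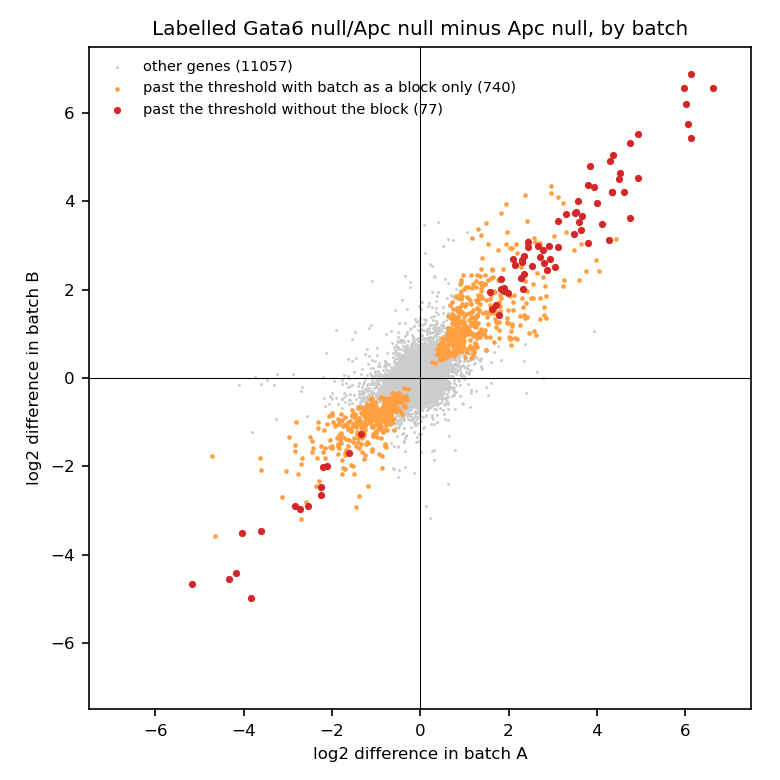
Log2 difference between the genotypes in batch A (horizontal axis) and batch B (vertical axis), 1 point per gene, red for the 77 genes past the threshold without a block and orange for the 740 that passed only with the batch as a block. The points run along the diagonal, with a correlation of 0.722 across genes.

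Among the BMP ligands, the signals named in the title of the series, Bmp7 was 7.03-fold higher in the arrays labelled Gata6 null/Apc null (log2 2.81, SE 0.23, adjusted p = 0.0253), at 7.62 ± 0.17 against 4.80 ± 0.01. It was higher by 2.94 in batch A and by 2.69 in batch B. Its adjusted p was 0.102 without the Apc null array of batch A and 0.0895 without that of batch B. Bmp7 was the single member of 7 tested that passed the threshold over all genes. Adjusted over the list alone, 1 member was higher, Bmp7, and 1 lower, Bmp8b. Bmp2 had a difference of 2.21 (SE 0.73) that did not pass (adjusted p = 0.492) but did with the batch as a block (adjusted p = 0.00939), with 2.80 in batch A and 1.61 in batch B, and 1.21 without the Apc null array of batch A. Bmp6 differed by 1.40 (SE 0.65, adjusted p = 0.790), with 0.63 in batch A and 2.16 in batch B. Bmp8b went the other way, by -1.43 (SE 0.22, adjusted p = 0.105, and 0.00511 with the block). Bmp4, chosen after its values were seen, differed by 0.75 (SE 0.30, adjusted p = 0.641, and 0.142 with the block). It read 5.11 against 4.79 in batch A and 5.89 against 4.70 in batch B, so most of its difference came from batch B. The mean over the 7 ligands was 0.80, with 0.76 in batch A and 0.84 in batch B. The camera test of the list missed the threshold (adjusted p = 0.0535, or adjusted p = 0.317 with an estimated correlation). It passed with the batch as a block (adjusted p = 0.0457), but not with the block and an estimated correlation (adjusted p = 0.502). It missed the threshold without the Apc null array of batch A (0.0595) and passed without the Gata6 null/Apc null array of batch A (0.0233), without that of batch B (0.0299) and without the Apc null array of batch B (0.0189).

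The BMP response genes, which are transcribed when BMP receptors activate SMAD proteins, were higher as a list in the arrays labelled Gata6 null/Apc null. Their mean log2 difference was 0.78 over 14 genes tested, 0.83 in batch A and 0.74 in batch B, and the camera adjusted p was 6.81e-07. The adjusted p was 0.317 with an estimated correlation. No member passed over all genes, 6 were higher when adjusted over the list alone, and 7 were higher with the batch as a block. The leading members were Bambi, a decoy receptor of the pathway, with a difference of 1.67 (SE 0.30, adjusted p = 0.146, and 0.00693 with the block), and the homeobox gene Dlx3 with 2.03 (SE 0.39, adjusted p = 0.169, and 0.00748 with the block). Bambi is also in the Wnt target list, so its difference counts in both lists. The other Dlx3 probe set read 4.67 to 5.39 and differed by 0.36 (limma adjusted p = 0.556 over all probe sets with the block). As the mean of all its probe sets Dlx3 differed by 1.19 (adjusted p = 0.328). The other list members past the threshold with the block, chosen after their values were seen, were the inhibitor of differentiation genes Id2 (0.90) and Id3 (1.89), the inhibitory SMAD genes Smad6 (1.27) and Smad7 (1.07), and Tsc22d1 (0.50). The BMP antagonists had a mean of 0.49 over 8 genes tested (camera adjusted p = 0.0329, or adjusted p = 0.317 with an estimated correlation), with none past the threshold over all genes and 1 higher when adjusted over the list alone. That gene was Fst, the activin and BMP binding protein follistatin, with a difference of 2.74 (SE 0.33, adjusted p = 0.0583, and 0.00467 with the block), followed by Nbl1 with 0.66 (adjusted p = 0.459). The adjusted p of the antagonist list was 0.167 without the Apc null array of batch A and 0.108 without the Gata6 null/Apc null array of batch B. The BMP receptors and SMADs were not shifted as a list, with a mean of 0.06 and a median of -0.04 over 12 genes (camera adjusted p = 0.528), and no member passed by either adjustment. Smad1, a transducer of the pathway, differed by 0.99 (adjusted p = 0.206, and 0.0155 with the block), and the co-receptor gene Rgmb differed by -0.68 (adjusted p = 0.617).

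**Figure D3:**
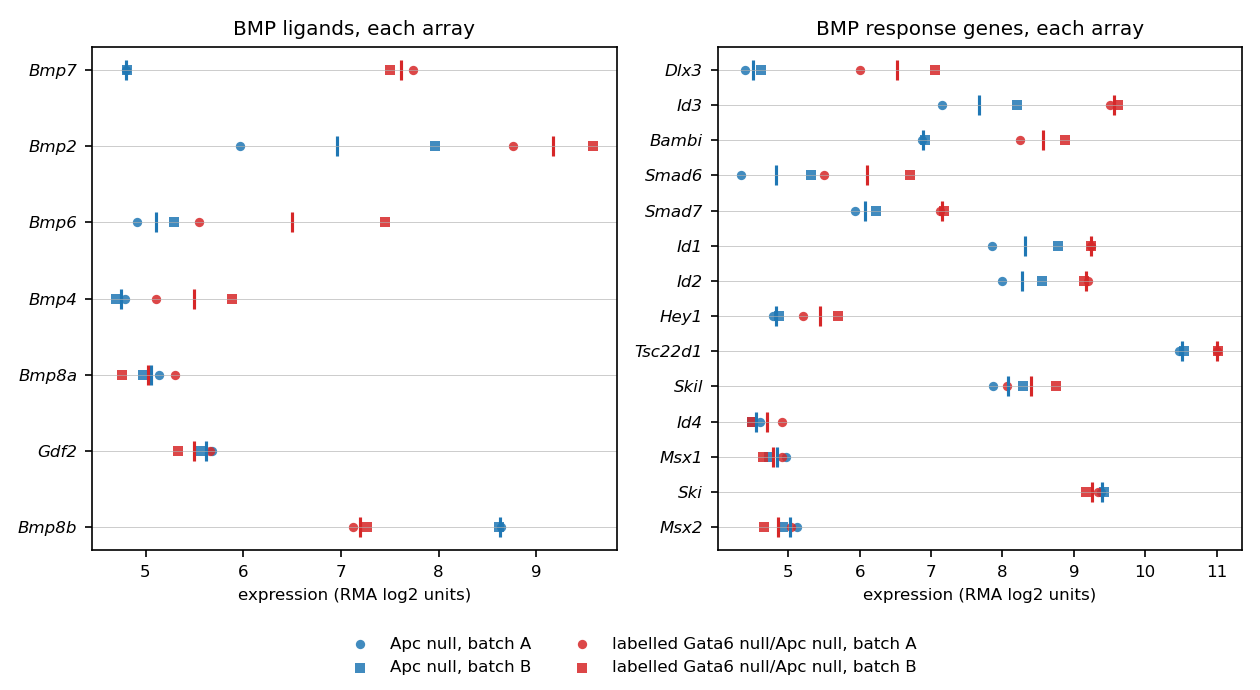
Expression in log2 units (horizontal axes) of the 7 BMP ligands and 14 BMP response genes tested on each of the 4 arrays, with circles for batch A, squares for batch B and vertical bars for group means. Bmp7 lies at 7.62 on average in the arrays labelled Gata6 null/Apc null and at 4.80 in the Apc null arrays, while Bmp8b lies at 7.19 and 8.63.

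Wnt target genes had the largest mean increase of the 29 lists over both batches, although in batch A the tuft cell markers had a larger one (1.46 against 1.41). Of 29 Wnt target genes tested, 6 were higher and none lower over all genes, while 13 were higher and 3 lower when adjusted over the list alone. Of these 6, Apcdd1, Wif1, Notum and Nkd1 encode inhibitors of the pathway, a grouping made after their values were seen and not tested. Besides Apcdd1 and Wif1, Notum, a secreted enzyme that inactivates Wnt ligands, was 22.8-fold higher (log2 4.51, SE 0.22, adjusted p = 0.0126), and the Dishevelled antagonist gene Nkd1 was 15.7-fold higher (log2 3.98, SE 0.22, adjusted p = 0.0137). The remaining calls were Prox1 and the transcription factor gene Lef1, which was higher by 4.29 and was chosen after its values were seen. The list mean was 1.43 (median 0.46), with 1.41 in batch A and 1.45 in batch B, and the camera adjusted p was 1.20e-07. The adjusted p was 0.317 with an estimated correlation. With the batch as a block, 13 members were higher and 5 lower. The 5 lower members were Lgr5, Myc, Mmp7, Jag1 and Plaur, of which Myc, Mmp7, Jag1 and Plaur were chosen after their values were seen and had differences of -0.59, -0.78, -1.17 and -0.80.

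Intestinal stem cell markers, several of which, Lgr5 and Znrf3 among them, are also in the Wnt target list, did not shift as a list. The mean over 23 genes was -0.21 (-0.22 in batch A and -0.19 in batch B), with a camera adjusted p of 0.129, and no member passed over all genes. Adjusted over the list alone, 1 was higher and 4 were lower. Lgr5, the R-spondin receptor that marks crypt base stem cells, differed by -2.47 (SE 0.46), at 6.97 ± 0.82 against 9.44 ± 0.39, with an adjusted p of 0.161 that became 0.00142 with the batch as a block. Znrf3, a ubiquitin ligase that removes Wnt receptors, differed by 1.62 (SE 0.34, adjusted p = 0.219, and 0.00377 with the block). The list passed, as lower, without the Apc null array of batch A (adjusted p = 0.0220) and without the Gata6 null/Apc null array of batch B (0.0439), but not without the other Apc null array (0.776) or the other Gata6 null/Apc null array (0.379). Cell cycle genes had a mean of -0.12 over 33 genes and a camera adjusted p of 0.432, or 0.0338 with the block (adjusted p = 0.502 with the block and an estimated correlation). No cell cycle gene passed by either adjustment, and the members with the smallest p were Cenpf (0.19) and Cdt1 (-0.32), both at an adjusted p of 1.00. Their list mean turned with the arrays used. It was -0.48 without the Gata6 null/Apc null array of batch A and -0.50 without the Apc null array of batch B. It was 0.25 without the Apc null array of batch A and 0.23 without the Gata6 null/Apc null array of batch B. Cell cycle genes were lower in batch B by a mean of -0.73, and leaving out an array makes the batches unequal between the groups. These moves therefore do not separate genotype from batch.

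Goblet, Paneth, and absorptive colonocyte and enterocyte markers were lower as lists in camera with the preset correlation. Among the goblet cell markers, Spink4 was the single member of 16 that was lower over all genes, and 6 were lower when adjusted over the list alone. The goblet list had a mean of -1.14 (-1.25 in batch A and -1.04 in batch B, camera adjusted p = 2.39e-07, or 0.317 with an estimated correlation). Of 8 Paneth and deep crypt secretory markers, Lyz2 and Spink4 were lower over all genes and 4 were lower when adjusted over the list alone. This list had a mean of -1.65 (-1.52 and -1.78 in batches A and B, camera adjusted p = 9.54e-07, or 0.317 with an estimated correlation). Of 24 absorptive colonocyte and enterocyte markers, none passed over all genes and 4 were lower when adjusted over the list alone, with a mean of -0.63 (-0.68 and -0.58 in batches A and B, camera adjusted p = 3.72e-07, or 0.317 with an estimated correlation). The smallest p among them belonged to the hormone genes Guca2a (-2.95, SE 0.33, adjusted p = 0.0530, and 0.00110 with the block) and Guca2b (-1.98, SE 0.32, adjusted p = 0.119, and 0.00309 with the block). With the block 10 of these 24 were lower and 1 higher. These 3 lists overlap, since Spink4 and Reg4 are in the goblet and Paneth lists and Guca2a is in the goblet and absorptive lists. Of 20 tuft cell markers in the list, 16 were on the array, and most of these were too dim to be tested. The 4 tuft cell markers tested were higher as a list (mean 1.38, 1.46 in batch A and 1.30 in batch B, camera adjusted p = 0.00203, or adjusted p = 0.325 with an estimated correlation). None passed over all genes and 2 were higher when adjusted over the list alone: Hpgds, a prostaglandin D synthase (2.51, adjusted p = 0.0968), and Avil, an actin regulator (2.67, adjusted p = 0.140), each at 0.00467 with the block.

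Enteroendocrine markers did not shift as a list (mean -0.19 over 15 genes, camera adjusted p = 0.216), and none passed by either adjustment. Chga differed by -0.51 (adjusted p = 0.575) and Insm1 by -1.91 (adjusted p = 0.638, and 0.0470 with the block), with -2.82 in batch A and -0.99 in batch B. Insm1 read 6.73 and 4.49 in the Apc null arrays of batches A and B, and its difference was -0.79 (adjusted p = 0.593) without the former and -3.03 (0.0381) without the latter. The list passed, as lower, without either array of batch A (0.0453 and 0.0351), but not without either array of batch B (0.418 and 0.953). Small intestine absorptive genes had a mean of 0.17 over 12 genes (camera adjusted p = 0.825) with 1 higher when adjusted over the list alone, the receptor gene Cubn (2.51, adjusted p = 0.105, and 0.00293 with the block). Apob in that list differed by -0.68 (adjusted p = 0.341). Gastric and foregut genes had a mean of -0.25 over 13 genes (camera adjusted p = 0.440). None passed over all genes, and adjusted over the list alone the mucin gene Muc1 was lower (-2.84, adjusted p = 0.0968, and 0.00818 with the block) and Sox21 higher (0.55, adjusted p = 0.168, and 0.0103 with the block).

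Hox genes of the hindgut, which set position along the gut, were higher as a list, with a mean of 0.53 over 14 genes tested (0.66 in batch A and 0.40 in batch B, camera adjusted p = 0.00359, or adjusted p = 0.317 with an estimated correlation). None passed over all genes, and 6 were higher and 1 lower when adjusted over the list alone. Hoxb13 differed by 0.69 (adjusted p = 0.149, and 0.00786 with the block) and Hoxa11, the lower gene, by -1.11 (adjusted p = 0.118, and 0.0181 with the block). Fetal and regenerative epithelium genes were lower as a list, with a mean of -0.74 over 16 genes (-1.00 in batch A and -0.47 in batch B, camera adjusted p = 1.11e-04, or adjusted p = 0.317 with an estimated correlation). No member passed by either adjustment and 7 were lower with the block, among them the chaperone gene Clu (-1.68, adjusted p = 0.234, and 0.00114 with the block) and the interleukin 1 receptor antagonist gene Il1rn (-1.04, adjusted p = 0.198, and 0.00831 with the block). The mean of this list was -0.39 without the Gata6 null/Apc null array of batch A.

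Stress and metabolic lists were lower too. Unfolded protein response genes had a mean of -0.41 over 21 genes (-0.47 in batch A and -0.35 in batch B, camera adjusted p = 7.02e-05, or adjusted p = 0.317 with an estimated correlation). None passed by either adjustment. The leading members were Asns (-0.93, adjusted p = 0.195, and 0.00606 with the block), which makes asparagine, and Trib3 (-1.70, adjusted p = 0.387, and 0.00542 with the block), a pseudokinase. Both are known targets of the transcription factor ATF4. Cholesterol biosynthesis genes had a mean of -0.30 over 17 genes (-0.39 and -0.21 in batches A and B, camera adjusted p = 0.00203), and none passed by either adjustment, with Fdps at -0.38 (adjusted p = 0.593) and Dhcr7 at -0.32 (adjusted p = 0.856). That list had an adjusted p of 0.317 with an estimated correlation, 0.198 without the Gata6 null/Apc null array of batch A (mean -0.18) and 0.0560 without the Apc null array of batch B. Immediate early genes had a mean of -0.23 over 20 genes (-0.27 and -0.19 in batches A and B, camera adjusted p = 0.0329, or 0.317 with an estimated correlation), and none passed by either adjustment. Jun differed by 0.87 (adjusted p = 0.272, and 0.0215 with the block) and Klf6 by -0.62 (adjusted p = 0.284, and 0.0200 with the block). The adjusted p of this list was 0.0740 with the block, 0.198 without the Gata6 null/Apc null array of batch A and 0.368 without the Apc null array of batch B.

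Hypoxia and glycolysis genes did not keep their difference from batch to batch. The mean over 21 genes was -0.65 (camera adjusted p = 0.0110, or 0.651 with an estimated correlation), made of -1.30 in batch A and 0.01 in batch B. Whether the genotype difference itself differed between the batches was not tested. No member passed by either adjustment or with the block, and Slc2a1 (-0.61, adjusted p = 0.993) and Pfkl (-0.63, adjusted p = 1.00) had the smallest p. Without the Gata6 null/Apc null array of batch A the mean turned to 0.39, and without that of batch B it was -1.68. Without the Apc null array of batch A it was -1.03, and without that of batch B it was -0.27. Hypoxia and glycolysis genes were higher in batch B by a mean of 1.42, and leaving out an array makes the batches unequal between the groups. These moves therefore mix batch with genotype.

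Markers of cells other than epithelium were tested alongside. In the fibroblast list, 2 of 9 genes tested were higher over all genes and when adjusted over the list alone: Mgp, and Vim, the intermediate filament vimentin, which was 17.5-fold higher (log2 4.13, SE 0.27, adjusted p = 0.0157). The list mean was 1.02 (1.08 in batch A and 0.95 in batch B, camera adjusted p = 0.0419) but the median was 0.01. The adjusted p was 0.317 with an estimated correlation and 0.641 without the Gata6 null/Apc null array of batch A. Immune cell markers had a mean of -0.41 over 14 genes (camera adjusted p = 0.131, or 0.0434 without the Apc null array of batch A), and the 1 lower member by either adjustment was Lyz2, which is also in the Paneth list. Endothelial markers had a mean of 0.08 over 7 genes (camera adjusted p = 0.432) and none passed by either adjustment, with Sox18 at 0.35 (adjusted p = 0.717) and Eng at -0.15 (adjusted p = 1.00). Y-linked genes had a mean of 0.60 over 4 genes tested, 0.89 in batch A and 0.32 in batch B, with a camera adjusted p of 0.0542, or 0.0338 with the block (adjusted p = 0.502 with the block and an estimated correlation), and none passed by either adjustment. This list passed without the Apc null array of batch B (0.0452) and without the Gata6 null/Apc null array of batch B (0.0439), but not without either array of batch A (0.160 and 0.302). Usp9y read 7.36 in the Gata6 null/Apc null array of batch A and 4.50 to 4.58 in the other 3 arrays, a difference of 1.39 (adjusted p = 1.00), and Uty differed by 0.33 (adjusted p = 1.00).

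Notch pathway genes did not shift as a list (mean -0.11 over 20 genes, camera adjusted p = 0.558). None passed by either adjustment, with Hes6 at 0.77 (adjusted p = 0.209, and 0.00793 with the block) and Notch1 at 1.06 (adjusted p = 0.370, and 0.0393 with the block), or 0.69 without the Gata6 null/Apc null array of batch A. With the block 4 members were lower, chosen after their values were seen: Atoh1 (-1.20), Jag1, Dll1 (-0.80) and Dtx4 (-0.58). Interferon response genes had a mean of -0.24 over 17 genes (camera adjusted p = 0.182), with Ifitm3 at 0.50 (adjusted p = 0.167, and 0.00939 with the block) and Oasl1 at -0.92 (adjusted p = 0.531). The mean of this list was -0.56 without the Apc null array of batch A and -0.45 without the Gata6 null/Apc null array of batch B. It was -0.03 without the Gata6 null/Apc null array of batch A and turned to 0.08 without the Apc null array of batch B. These moves do not separate genotype from batch, since the list was higher in batch B by a mean of 0.53. Inflammatory and NF-kB genes had a mean of -0.05 over 18 genes, -0.34 in batch A and 0.23 in batch B (camera adjusted p = 0.145). The mean turned to 0.08 without the Gata6 null/Apc null array of batch A and to 0.10 without the Apc null array of batch A. In that list were Cxcl16 at -1.07 (adjusted p = 0.208, and 0.0178 with the block) and Tnfaip3 at -0.97 (adjusted p = 0.399). Genes of p53 and apoptosis had a mean of -0.17 over 19 genes, -0.04 in batch A and -0.31 in batch B, with a camera adjusted p of 0.0523, or 0.0442 with the block (adjusted p = 0.680 with the block and an estimated correlation). The mean of that list was -0.41 without the Apc null array of batch A and -0.27 without the Gata6 null/Apc null array of batch B. It was -0.08 without the Gata6 null/Apc null array of batch A and turned to 0.06 without the Apc null array of batch B. The list was higher in batch B by a mean of 0.32, so these moves also mix batch with genotype. In it Ccng1 differed by -0.34 (adjusted p = 0.624) and Perp by -0.50 (adjusted p = 0.691, and 0.0464 with the block), or -0.26 without the Apc null array of batch B. No interferon, inflammatory or p53 gene passed by either adjustment.

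Of the 29 lists, 15 passed with the preset inter-gene correlation, 7 higher and 8 lower. None passed with an estimated correlation, where the smallest adjusted p was 0.317 and 2 lists, the goblet and absorptive markers, had an unadjusted p under 0.05. The rotation test fry, which asks whether the members of a list move one way without comparing them with other genes, passed 2 lists, the BMP ligands (adjusted p = 0.0229) and the absorptive markers (adjusted p = 0.0342). With the batch as a block, 18 lists passed in camera, none in camera with an estimated correlation (smallest adjusted p = 0.502) and none in fry. The calls of 9 lists held without each array in turn: Wnt targets, goblet, absorptive, BMP response, Paneth, unfolded protein response, fetal, tuft and Hox genes. With the block, further members of several lists passed, named here after their values were seen. They were the stem cell markers Aqp4 (-3.24), Kcnq1 (-0.78), Prom1 (-0.53) and Slc12a2 (-0.48), the Hox genes Hoxd10 (1.82), Hoxd13 (1.74), Hoxd11 (1.67) and Hoxb9 (1.38), and in the unfolded protein response Chac1 (-1.52). Among immediate early genes they were Fos (-1.36) and Myc, among interferon genes Usp18 (0.88) and Ifi27 (-0.77), and in 3 other lists Cxcl5 (1.27), Trp53inp1 (0.80) and Mgam (-0.65). In the goblet list 7 were lower with the block, and in the Paneth list 4: Lyz2, Spink4, Reg4 and Mmp7.

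**Figure D4:**
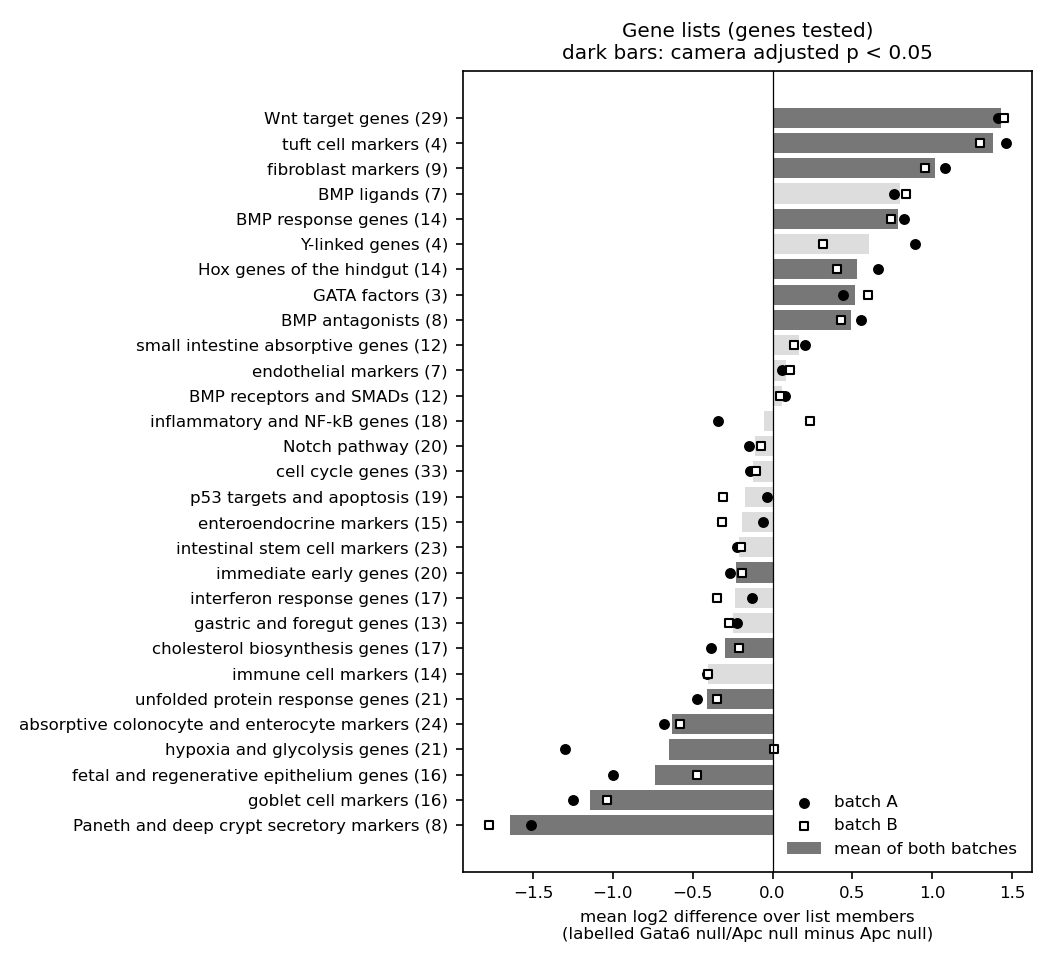
Mean log2 difference (horizontal axis) over the tested members of each of the 29 gene lists, arrays labelled Gata6 null/Apc null minus Apc null, with the number of genes tested in brackets. Bars give the mean of both batches, dark where the camera adjusted p was under 0.05, with filled circles for batch A and open squares for batch B; the hypoxia list has its batches at -1.30 and 0.01.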

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

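The fit of probe sets outside the gene comparison was chosen after the data were seen. Among 7796 probe sets without a single gene name above the filter level, 13 passed the threshold in limma, 12 higher and 1 lower in the arrays labelled Gata6 null/Apc null. They are listed because no comparison by gene uses them. Most were brighter than in the control arrays, those labelled Apc null, as were 62 of the 77 genes called above. In the same fit, 54 of 27022 probe sets with and without a name passed, these 13 among them. That is a similar share, so the unnamed probe sets do not stand out in number or direction. With the batch as a block, 257 of the 7796 passed.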

How the results depend on the processing

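The fit of all probe sets was chosen after seeing the data. So were, for each list other than the BMP ligands, the tests with arrays left out or with the block. The other alternatives were planned. The batch letter as a random block was not run, because its correlation could not be estimated from 4 arrays. With the replicate block as a fixed term, the counts were 817 genes, 464 higher and 353 lower, against 77, 62 and 15 without it. The mean of the BMP ligands stayed at 0.80 and passed (camera adjusted p = 0.0457). Gata6 stayed at 0.64 at its brighter probe set and passed (limma adjusted p = 0.0392), while its other probe set did not (0.178 over all probe sets). The share of higher genes was 56.8% with the block and 80.5% without it. The block made 30 named genes other than Gata6 pass, ended the call of none and changed 5 of the list calls, each given with its list. It changed no other call of a list in camera or of a gene named by the rule. Calls it changed among genes named after their values were seen are given with those genes, and fry called 0 lists with it. Median centring gave 126 genes, 102 higher and 24 lower, and a threshold of 0.1 gave 149, 113 higher and 36 lower. The BMP ligands passed after median centring (mean 0.81, adjusted p = 0.0313), with the filter at the 60th percentile (1.25, 0.0451), at a threshold of 0.1 (0.80, 0.0535) and with fry (0.80, 0.0229), and had a mean of 0.43 without a filter (0.133). Their adjusted p ranged from 0.0189 to 0.502, the latter with the block and an estimated correlation. Camera with an estimated correlation called 0 lists and fry called 2, against 15. Without each array in turn, the count of genes ran from 33 to 130, higher genes from 24 to 118, lower genes from 9 to 12 and the BMP ligand mean from 0.62 to 0.98. Leaving out an array also makes the batches unequal between the groups, and the BMP ligand mean was 0.32 higher in batch B than in batch A. The cause of these changes was not tested, beyond the fewer arrays, the unequal batches and the looser threshold.

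The other settings gave 67 genes without a trend, 74 with robust moderation, 80 without a filter, 53 with the 60th percentile, 61 with mean probe sets, 70 without shared-sequence probe sets, 86 with quantile normalization and 54 of all probe sets. Of the 77 genes, 66 passed without a trend, 74 with robust moderation, 75 without a filter, 76 with quantile normalization and 77 with median centring. Of those still tested, 52 of 55 passed with the stricter filter, 58 of 74 with mean probe sets and 69 of 72 without shared-sequence probe sets. Without the Apc null array of batch A 28 of the 77 passed, without that of batch B 37, without the Gata6 null/Apc null array of batch A 63 and without that of batch B 57. Each of the 77 kept its sign wherever it was tested. Over all settings and all named genes other than Gata6, 971 values stayed on their side of the threshold with the same sign. A further 47 passed it newly, 40 no longer passed and 4 turned sign, none of them past the threshold before. Apc turned to 0.041 as the mean of all its probe sets. Usp9y ranged from -0.035 without the Gata6 null/Apc null array of batch A to 2.82 without that of batch B, where it passed (adjusted p = 0.0267). Cdt1 ranged from -0.70 to 0.058 over the arrays left out, turning to 0.039 without the Apc null array of batch A. Dim signal limits the folds: 29 of 62 higher genes lay under the filter level in the Apc null arrays, and 4 of 15 lower genes did in the arrays labelled Gata6 null/Apc null.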

Other observations

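The gene families, the tests between batches and the tests of explanations below were chosen after the results were seen. Of 3 metallothioneins tested, Mt3 and Mt4 were higher and Mt1, already bright at 10.80 in the Apc null arrays, differed by 0.46 (adjusted p = 0.449). Of 19 zinc transporters, Slc30a2 was the single one past the threshold, and with the batch as a block the importers Slc39a8 (1.43) and Slc39a6 (1.01) also passed. Of 8 homeobox genes of the Irx, Meis and Evx families, 3 were higher: Irx5 by 4.32, Meis2 by 2.84 and Evx1 by 2.49. Of 16 glutathione S-transferases, Gstm7 was higher by 3.67 and Gsta2 lower by the amount given above, and 2 were higher and 4 lower with the block. Of 11 claudins Cldn2 alone was lower, joined by Cldn4 (-0.81) with the block. Of 6 neuropilin, Robo and Slit genes, Robo1 was higher and Nrp1 lower.

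With batch and genotype in the same model, 1977 genes differed between batches, against 817 between genotypes. Of the 1977, 894 were higher and 1083 lower in batch B. Cell cycle genes were lower in batch B, by a mean of -0.73 with 24 of 33 past the threshold (camera adjusted p = 2.98e-14). Hypoxia and glycolysis genes were higher by 1.42 with 16 of 21 past it (camera adjusted p = 1.69e-11), and interferon response genes by 0.53 (camera adjusted p = 2.82e-04). Lrg1, a secreted glycoprotein gene, was higher in batch B by 3.35 and the growth factor binding protein gene Igfbp4 by 2.74.

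Gata6 signal was no lower in the arrays labelled Gata6 null/Apc null. A single mislabelled array is argued against by the correlation of 0.722 across genes between the differences of batch A and batch B, since a wrong label on an array of either batch would remove the shared differences. Group labels exchanged in both batches cannot be told apart from correct ones, as the log2 difference of 0.64 comes from a probe set of unknown position relative to the deletion. Signal from a part of the transcript that the deletion leaves may account for the level of 9.39 in these arrays, and it stays open for the same reason. No biological explanation was tested.

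Wnt target genes had the smallest camera p of the 29 lists. A uniform rise of Wnt target genes is argued against by the 5 members given above as lower with the batch as a block, Lgr5 among them. This restates that result and is no separate test, and 10.1% of that fit's calls on simulated data were false. Scaling between arrays, which keeps the order of genes within an array, is argued against: 12 of the 29 members rose in rank by more than 25 percentile points in both batches, as did 1.12% of all genes. A different extent of Apc deletion between the groups cannot be told apart from an effect of genotype, as the 4 Apc probe sets, of unknown position relative to its deletion, differed by -0.12 to 0.27, with -0.10 at the brightest. The genotype named by the labels stays among the open explanations as a hypothesis, untested apart from the comparison itself.

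Vim and Mgp were higher by 4.13 and 5.03, and both are abundant in mesenchyme. Mesenchymal or endothelial cells in the cultures are argued against: the other 38 fibroblast and endothelial markers on the array had a median log2 difference of -0.0255 (SD 0.14, range -0.33 to 0.35), and Col1a1, Col1a2, Col3a1, Sparc and Dcn, which such cells hold in abundance, stayed at 3.81 to 4.51 log2 units in the arrays labelled Gata6 null/Apc null. Of these markers 1, Eng, is also in the list of BMP receptors. Expression of both genes in the epithelial cells of the arrays labelled Gata6 null/Apc null is a hypothesis that these arrays did not test, and other cell types were covered here by the immune list alone.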
